A study of Mus musculus with 18 samples.

How the data were processed

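The 18 libraries were read as the submitters' count per gene. Their processing notes give polyA RNA, reads aligned to the mouse genome (mm10) with STAR 2.7.4a, sorting with SAMtools 1.12 and counting with featureCounts 1.6.0, followed by DESeq2 1.26.0. The counts are whole numbers of read pairs assigned to a single gene, without strand, over 55401 genes, so a read from an antisense transcript inside another gene's exons counts for that gene, and reads that fit several copies of a gene are left out. Symbols were matched by Ensembl gene identifier to a GENCODE mouse release, which gave 55141 of the genes a symbol, and positions are those of mm10. 0 library columns failed to match a sample. Among the gene lists, 1 symbol was matched through a synonym and 1 was not matched. No library repeated the counts of another in its group.

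Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr on the groups of each fit, libraries were scaled by TMM factors, and a quasi-likelihood F-test was made for each gene, with Benjamini-Hochberg adjustment over the genes of a comparison and an adjusted p under 0.05 as the threshold for a call. The 12 untreated libraries shared one fit with a mean per group (8 residual degrees of freedom), from which came PLD against WT at 1 and at 2 months, 2 months against 1 month within each genotype, and the interaction. CPTH6 and ML324 were compared in a fit of their 6 libraries (4 residual degrees of freedom). Each was compared with untreated PLD at 2 months in a fit of those 9 libraries (6 residual degrees of freedom). Standard errors are the log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log2 CPM adds a prior count of 2.

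In all, 55 gene lists were fixed: pathways, cell type markers, stress and chromatin genes that fit bile ducts and the compounds. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, then again with an estimated correlation, and with fry, whose directional test asks whether a list's genes move one way on balance. Marker lists describe cells that a bead preparation of minced bile ducts could hold and identify no cell in a library. Genes were named by a fixed rule: per comparison, the 6 largest positive and the 6 largest negative changes among called genes without overlap between the groups and with a mean of at least 10 CPM, up to 4 called members of each list described with the smallest adjusted p (2 where none was called), and a short set of genes of the disease, the cell type and the targets of the compounds. Predicted genes without a proper symbol were left out, and some genes that met the rule are not reported here. The comparisons, lists, naming rule, thresholds and most alternative settings were chosen before the data were examined. Alternatives chosen after the data were seen are the covariates of endothelial markers, of fibroblast markers and of both, and the fit without WT replicate 3 at 1 month and WT replicate 1 at 2 months.

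The tests were tried on simulated counts with the depth and spread of each comparison, in which single genes were changed by a known fold. Of genes changed 2-fold, edgeR called 29.9% in PLD against WT at 1 month, 28.4% at 2 months, 22.4% for time in PLD, 19.4% for time in WT, 4.48% in the interaction, 46.3% between the compounds, 47.8% for CPTH6 and 34.3% for ML324 against PLD. At 4-fold the shares were 68.2%, 68.2%, 53%, 68.2%, 53%, 77.3%, 74.2% and 65.2% in the same order. Per comparison, edgeR called 0 to 9 unchanged genes. At 1 month, with all 3 tools tried, edgeR called 4, limma-voom 3 and DESeq2 36, and no changed gene was called the wrong way. With a list raised, camera called it and 0 others of 52. Correlation between genes was not simulated, so the preset was not tested.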

Results

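RNA was measured in 18 libraries of primary cholangiocytes, the epithelial cells that line the bile ducts, from wild-type (WT) mice and from mice with polycystic liver disease (PLD), in which bile ducts widen into cysts. The cells came from perfused livers whose parenchyma had been removed, and were captured with beads carrying an antibody to the epithelial surface protein EpCAM. The libraries form 6 groups of 3: WT and PLD at 1 month and at 2 months after tamoxifen, and PLD mice treated with CPTH6 or with ML324, whose library titles give 3 months. CPTH6 is known as an inhibitor of the histone acetyltransferases Kat2a and Kat2b, and ML324 as an inhibitor of the KDM4 histone demethylases. Total counts per library ran from 16345740 in ML324 replicate 2 to 29277311 in PLD replicate 2 at 1 month. Between 22780 and 30332 genes had a count in each library except WT replicate 1 at 2 months, which had 40039, of which 19502 held 1 to 9 counts. The labels do not state whether replicates are separate animals or separate cultures, so every p-value measures only the spread between these samples, which may be technical. Changes below are log2 fold changes ± standard error with n = 3 libraries per group, levels are CPM (counts scaled by library size) ± SD, and genes named as higher or lower passed an adjusted p of 0.05 by edgeR unless the text says otherwise.

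The labels name no inactivated gene, and the known genes of polycystic disease were expressed in every group. Pkd1 (ENSMUSG00000032855.6, chromosome 17 from 24549834 to 24596508, mm10), which encodes polycystin-1, had 315 ± 102 CPM in WT and 229 ± 30.6 in PLD at 1 month, and 331 ± 36.9 and 197 ± 5.86 at 2 months. It stood at 108 ± 5.43 CPM after CPTH6 and 122 ± 10.7 after ML324. Pkd2 (ENSMUSG00000034462.9, chromosome 5 from 104459450 to 104505819), which encodes the channel protein polycystin-2, had 238 ± 16.7 CPM in WT and 339 ± 15.8 in PLD at 1 month, and 229 ± 22.2 and 358 ± 37.1 at 2 months. Pkhd1, which encodes the ciliary protein fibrocystin, had 180 ± 59.0 CPM in WT and 265 ± 60.0 in PLD at 2 months. For Prkcsh, which encodes a subunit of glucosidase II, those levels were 102 ± 13.9 and 167 ± 3.59 CPM, and for Sec63, a part of the protein translocation machinery of the endoplasmic reticulum, 142 ± 29.2 and 102 ± 2.92 CPM.

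The cell type markers of the libraries differed between groups. Cholangiocyte markers averaged 7.72 ± 0.71 log2 CPM (mean ± SD, n = 3) in WT and 8.84 ± 0.31 in PLD at 1 month, 7.14 ± 0.37 and 9.36 ± 0.04 at 2 months, 9.75 ± 0.16 after CPTH6 and 9.61 ± 0.11 after ML324. Endothelial markers averaged 7.60 ± 0.92, 7.74 ± 0.55, 9.04 ± 0.48, 5.71 ± 0.63, 3.97 ± 0.28 and 3.90 ± 1.35 in the same order of groups. The means of the stellate cell and fibroblast markers were 7.63 ± 1.34, 7.65 ± 0.28, 7.82 ± 0.33, 6.73 ± 0.17, 3.95 ± 0.04 and 4.05 ± 0.98. Within the WT group at 1 month, replicate 3 stood apart, with fibroblast markers at 6.09 against 8.37 and 8.44, endothelial markers at 6.57, and cholangiocyte markers at 8.53 against 7.37 and 7.26, above the 8.49 of PLD replicate 3 at 1 month. Its mean for epithelial junctions and polarity was 6.68 against 5.80 and 5.70, above that PLD library as well. In the ML324 group replicate 2 stood apart, with endothelial markers at 5.45 against 3.05 and 3.19 and stellate cell and fibroblast markers at 5.15 against 3.29 and 3.71.

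**Figure D1:**
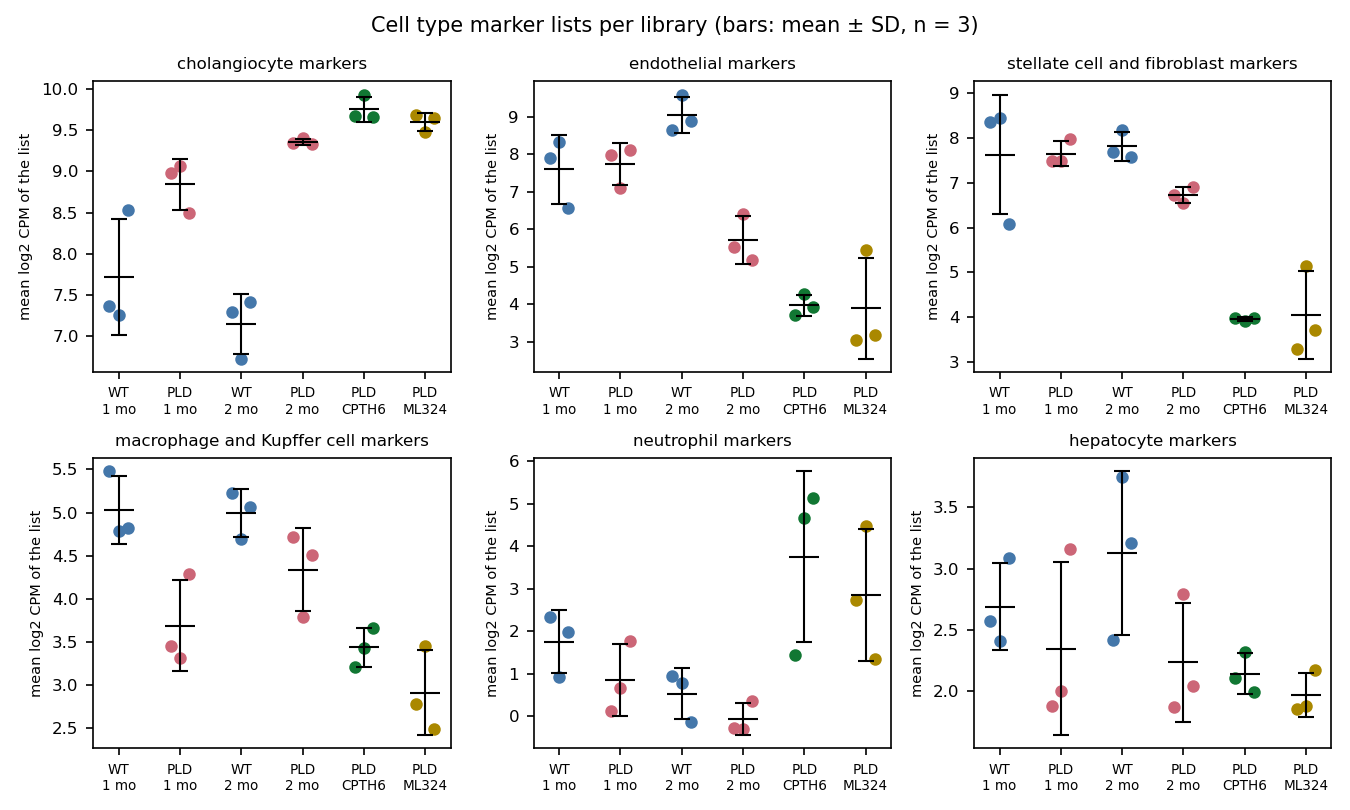
Mean log2 CPM of the measured members of 6 marker lists (vertical axes) in each of the 18 libraries, by group (horizontal axes). Points are libraries and bars give the mean ± SD of 3, and the endothelial markers are at 9.04 in WT and at 5.71 in PLD at 2 months.

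The first comparison asked how PLD libraries differed from WT libraries at 1 month. The largest changes are named first, without a theme tested over them. Psca (ENSMUSG00000022598.6, chromosome 15 from 74714839 to 74717069), which encodes a membrane-anchored surface protein first named for prostate stem cells, rose by 6.24 ± 0.70 (edgeR adjusted p = 0.00215), from 0.245 ± 0.161 to 19.3 ± 9.70 CPM. Anxa8 (an annexin, 4.98 ± 0.38), Esr1 (oestrogen receptor alpha, 4.70 ± 0.42) and Msln (mesothelin, 4.47 ± 0.32) were also higher. The pseudogene Rpl34-ps1 was higher by 6.09 ± 1.45, a value that reads shared with its parent gene or with other copies can move. Among genes that fell, Cd163, the haemoglobin scavenger receptor of macrophages, changed by -2.58 ± 0.66, Rgs1, a regulator of G-protein signalling in immune cells, by -2.35 ± 0.50, and Ccr2, a chemokine receptor of monocytes, by -1.97 ± 0.48. Ank2 (ankyrin-2, -2.85 ± 0.33), Kcnma1 (the pore of the BK potassium channel, -2.29 ± 0.34), Hspb7 (a small heat shock protein, -2.30 ± 0.50) and Tmod1 (tropomodulin, -2.16 ± 0.37) fell as well.

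Lists of epithelial identity and junction genes were called higher in PLD at 1 month by camera. Of the cholangiocyte markers, 5 of 20 rose and 0 fell, against 9 and 1 adjusted over the list alone (camera adjusted p = 2.71e-07, adjusted p = 0.756 with an estimated correlation). Krt19 (ENSMUSG00000020911.14, chromosome 11 from 100140810 to 100148665), the keratin used here to stain for purity, rose by 1.75 ± 0.33 from 405 ± 149 to 1358 ± 455 CPM. Krt7 rose by 2.43 ± 0.36 and the tetraspanin gene Tspan8 by 2.43 ± 0.26, while Epcam was not called at 0.64 ± 0.30 (adjusted p = 0.219, edgeR). Among genes of epithelial junctions and polarity, 8 of 29 rose and 0 fell, against 17 and 1 adjusted over the list alone (camera adjusted p = 1.46e-08, adjusted p = 0.756 with an estimated correlation). They included the tight junction genes Cldn4 at 1.85 ± 0.32 and Tjp3 at 1.38 ± 0.27. In the basement membrane list, 3 of 16 rose and 0 fell, against 4 and 0 adjusted over the list alone (camera adjusted p = 0.0058, adjusted p = 0.756 with an estimated correlation). One was the laminin chain gene Lamb3 at 2.32 ± 0.27. That call ended without WT replicate 3 (camera adjusted p = 0.205). Among the Wnt pathway targets, 4 of 19 rose and 0 fell, against 7 and 1 adjusted over the list alone (camera adjusted p = 0.0303, adjusted p = 0.756 with an estimated correlation). The ligand gene Wnt7a rose by 3.48 ± 0.32 and Axin2, a feedback inhibitor induced by Wnt signalling, by 1.21 ± 0.30, and the call for Wnt pathway targets ended without WT replicate 3 (camera adjusted p = 0.205). This list holds ligand genes beside targets, so it does not measure the output of the pathway alone. Endothelial markers were not called (median change -0.28, camera adjusted p = 0.941), and neither were fibroblast markers (-0.17, camera adjusted p = 0.95). Without WT replicate 3 the stellate cell and fibroblast markers were called lower (median -0.60, camera adjusted p = 0.00174). Of the polycystic disease genes, 1 of 12 rose, namely Pkd2 at 0.52 ± 0.12, while Pkd1 changed by -0.45 ± 0.21 without passing the test (adjusted p = 0.221, edgeR), and Pkhd1 (-0.09 ± 0.54), Prkcsh (0.29 ± 0.12) and Sec63 (-0.06 ± 0.16) were not called.

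By camera, lists of division, p53 response and sterol synthesis were called higher at 1 month, and immediate early genes and macrophage markers lower. The directional fry test called only the p53 targets at 1 month (fry adjusted p = 0.005). In mitosis and cell cycle progression, 3 of 30 rose and 0 fell, against 19 and 0 adjusted over the list alone (camera adjusted p = 3.09e-09, adjusted p = 0.756 with an estimated correlation). Among them were Cdc20, the activator of the anaphase-promoting complex, at 1.76 ± 0.33 and the kinesin gene Kif23 at 2.17 ± 0.42. DNA replication was called higher as a list with a median change of 0.48 and 0 of 30 members called, 0 adjusted over the list alone (camera adjusted p = 8.42e-06, adjusted p = 0.873 with an estimated correlation). Among p53 targets, 4 of 20 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 3.09e-06, adjusted p = 0.242 with an estimated correlation). They included Perp, a desmosome protein gene, at 1.35 ± 0.26 and Zmat3 at 0.69 ± 0.15. In sterol synthesis, 4 of 24 rose and 0 fell, against 14 and 0 adjusted over the list alone (camera adjusted p = 6.35e-07, adjusted p = 0.756 with an estimated correlation). Insig1, a regulator of the pathway, rose by 1.35 ± 0.30 (adjusted p = 0.0318, edgeR). The NRF2 list for oxidative stress defence had 3 of 22 members higher and 8 adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.873 with an estimated correlation). Its call ended without WT replicate 2 (camera adjusted p = 0.108). Immediate early genes went the other way, and 0 of 23 rose and 4 fell, against 0 and 8 adjusted over the list alone (camera adjusted p = 0.000516, adjusted p = 0.873 with an estimated correlation). Examples were the transcription factor genes Egr1 at -1.35 ± 0.28 and Egr3 at -1.51 ± 0.23. Of cAMP signalling genes, 0 of 25 rose and 2 fell, against 1 and 5 adjusted over the list alone (camera adjusted p = 0.002, adjusted p = 0.756 with an estimated correlation). Macrophage and Kupffer cell markers fell, with 2 of 18 called, 13 adjusted over the list alone and a median of -1.64 (camera adjusted p = 4.51e-06, adjusted p = 0.756 with an estimated correlation). The dendritic cell and MHC class II genes had a median of -1.42 with 0 of 15 called, 0 adjusted over the list alone (camera adjusted p = 0.00199, adjusted p = 0.756 with an estimated correlation). They missed the threshold without WT replicate 3 (camera adjusted p = 0.0502). Neutrophil markers (median -1.01, 0 of 11 called, 0 adjusted over the list alone) were called lower (camera adjusted p = 0.037, adjusted p = 0.873 with an estimated correlation). This call ended without PLD replicate 1 (0.225), PLD replicate 2 (0.099), WT replicate 1 (0.178) or WT replicate 3 (0.206). Ribosomal proteins (median 0.15, 0 of 35 called, 0 adjusted over the list alone) were called higher (camera adjusted p = 0.0058, adjusted p = 0.946 with an estimated correlation) but not without WT replicate 3 (camera adjusted p = 0.862).

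Over 17749 genes tested at 1 month, 892 were called by edgeR, 533 higher and 359 lower in PLD. DESeq2 called 2157, limma-voom 5842, and edgeR 29 when only the 6 libraries compared were fitted. Of 53 lists, 15 were called by camera, and in none of the 8 comparisons did a list call hold with an estimated correlation (0 lists). The count of genes was 3485 without WT replicate 3, 114 without PLD replicate 1, 99 without PLD replicate 2, 293 without WT replicate 1 and 274 without WT replicate 2, and 2 with the mean of macrophage markers as a covariate, of whose variance 76% lay between the groups. Of the 33 genes named for this comparison, 17 lost their call without PLD replicate 1, 19 without PLD replicate 2, 5 without PLD replicate 3, 14 without WT replicate 1, 13 without WT replicate 2 and 0 without WT replicate 3.

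At 2 months the same genotypes were compared again. Psca rose by 7.88 ± 0.70 (edgeR adjusted p = 7.66e-05), from 0.332 ± 0.370 to 85.5 ± 21.6 CPM. Krt20, a keratin of gut and urinary epithelium, rose by 7.83 ± 0.57, Msln by 6.70 ± 0.36, Anxa8 by 6.45 ± 0.40 and Tff3, which encodes a secreted trefoil peptide of mucous epithelia, by 6.36 ± 1.01 (adjusted p from 1.21e-05 to 0.000887, edgeR). Wnt9b and Rspo3, signals that liver endothelium makes for the Wnt pathway, fell (changes -4.97 ± 0.48 and -4.94 ± 0.42), and Rspo3 went from 243 ± 54.6 to 8.04 ± 3.12 CPM. The other largest falls were Cyp26b1, an enzyme that degrades retinoic acid (-5.42 ± 1.00), Plppr5 (-5.37 ± 0.79), Slc26a10 (-4.81 ± 0.42) and Fabp4, a fatty acid binding protein of capillary endothelium and fat (-4.77 ± 0.65), with adjusted p from 7.04e-05 to 0.00193.

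Epithelial genes rose together at 2 months while endothelial markers fell in the same libraries. Of the cholangiocyte markers, 16 of 20 rose and 0 fell, against 16 and 0 adjusted over the list alone (camera adjusted p = 7.71e-09, adjusted p = 0.862 with an estimated correlation). Among them were Krt19 at 3.64 ± 0.35 from 220 ± 48.4 to 2805 ± 231 CPM, Krt7 at 4.02 ± 0.39, the biliary transcription factor gene Sox9 at 2.04 ± 0.41 and Epcam at 1.87 ± 0.31. Every one of the 16 endothelial markers measured fell, 16 adjusted over the list alone (camera adjusted p = 7.71e-09, adjusted p = 0.862 with an estimated correlation). They included Tek, the angiopoietin receptor, at -4.03 ± 0.51 and Vwf, von Willebrand factor, at -3.31 ± 0.46. Among junction and polarity genes, 23 of 29 rose and 1 fell, against 25 and 2 adjusted over the list alone (camera adjusted p = 7.71e-09, adjusted p = 0.862 with an estimated correlation). Examples were Cldn4 at 2.95 ± 0.33 and Tjp3 at 2.38 ± 0.27. For ion and water transport of bile ducts, 11 of 19 rose and 1 fell, against 11 and 2 adjusted over the list alone (camera adjusted p = 0.0232, adjusted p = 0.862 with an estimated correlation). The calcium-activated chloride channel gene Ano1 rose by 2.66 ± 0.29 and the bile acid transporter gene Slc10a2 by 3.28 ± 0.48. Among the Wnt pathway targets, 10 of 19 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 0.00593, adjusted p = 0.862 with an estimated correlation). Among them were the ligand genes Wnt7a at 4.85 ± 0.34 and Wnt10a at 3.93 ± 0.35, which are not readouts of Wnt signalling. Fibroblast markers had 11 of 20 members lower and 1 higher and missed the threshold as a list (camera adjusted p = 0.0518), and macrophage markers had a median of -0.38. Hepatocyte markers went both ways, with 6 of 28 higher and 13 lower, and Alb, which encodes the serum protein albumin, rose by 2.62 ± 0.71. The basement membrane list differed in sign between its median (-0.34) and its test, which leaned upward without a call (camera adjusted p = 0.625).

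The polycystic disease genes split at 2 months. Pkd2 rose by 0.62 ± 0.12 and Prkcsh by 0.69 ± 0.12, Pkd1 fell (change -0.78 ± 0.21, adjusted p = 0.0142, edgeR) and so did Sec63 (change -0.50 ± 0.16), and Pkhd1 was not called at 0.53 ± 0.54. With the endothelial markers as a covariate, added after the data were seen, Pkd1 and Sec63 changed sign to 0.40 and 0.32 (adjusted p = 0.565 and 0.583, edgeR). In mitosis and cell cycle progression, 13 of 30 rose and 1 fell, against 13 and 1 adjusted over the list alone (camera adjusted p = 0.000351, adjusted p = 0.897 with an estimated correlation). They included Kif23 at 3.71 ± 0.45. DNA replication followed, where 13 of 30 rose and 0 fell, against 14 and 0 adjusted over the list alone (camera adjusted p = 0.000768, adjusted p = 0.897 with an estimated correlation). One was the licensing factor gene Cdt1 at 1.82 ± 0.24. For p53 targets, 10 of 20 rose and 0 fell, against 11 and 0 adjusted over the list alone (camera adjusted p = 0.00128, adjusted p = 0.862 with an estimated correlation). Among them was Perp at 2.88 ± 0.28. Fatty acid oxidation rose as a list, where 17 of 24 rose and 0 fell, against 17 and 0 adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.862 with an estimated correlation). They included Hadha, a subunit of the mitochondrial trifunctional enzyme, at 0.95 ± 0.12. Oxidative phosphorylation had a small median of 0.22, and 16 of 34 rose and 1 fell, against 16 and 1 adjusted over the list alone (camera adjusted p = 0.00593, adjusted p = 0.897 with an estimated correlation). Ribosomal protein genes rose by a median of 0.61, and 30 of 35 rose and 0 fell, against 30 and 0 adjusted over the list alone (camera adjusted p = 7.71e-09, adjusted p = 0.897 with an estimated correlation). Among NRF2 genes, 12 of 22 rose and 1 fell, against 12 and 1 adjusted over the list alone (camera adjusted p = 0.00362, adjusted p = 0.862 with an estimated correlation). They moved apart, with the glutathione transferase gene Gsta4 at 5.03 ± 0.48 and the quinone reductase gene Nqo1 at -2.88 ± 0.37. In the interferon response, 14 of 30 rose and 0 fell, against 14 and 0 adjusted over the list alone (camera adjusted p = 0.00768, adjusted p = 0.897 with an estimated correlation). Examples were Irf7, a transcription factor of that response, at 2.65 ± 0.61 and the antiviral gene Mx1 at 3.67 ± 0.89. The mean of the interferon genes was 7.69 log2 CPM in PLD replicate 2 against 5.42 and 6.07 in the other 2, and the call for interferon response ended without PLD replicate 2 (camera adjusted p = 0.168) and without WT replicate 3 (0.0604). Of cAMP signalling genes, 2 of 25 rose and 13 fell, against 2 and 16 adjusted over the list alone (camera adjusted p = 0.0298, adjusted p = 0.862 with an estimated correlation). That call ended without PLD replicate 3 (camera adjusted p = 0.0735) and without the filter on low counts (0.0586). Areg, which encodes the growth factor amphiregulin, rose by 5.91 ± 0.57.

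At 2 months 7091 of 17749 genes were called by edgeR, 3490 higher and 3601 lower in PLD. With the mean of the endothelial markers as a covariate, an alternative added after the data were seen, 183 genes were called, 131 of them among the 7091. That covariate nearly repeats the genotype, since 93% of its variance lay between the groups and the median standard error rose from 0.263 to 0.516, so a loss of calls was expected from the design. Of the 38 genes named for this comparison, 26 lost their call with that covariate in the same direction, and 3 more lost it with a change of sign.

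**Figure D2:**
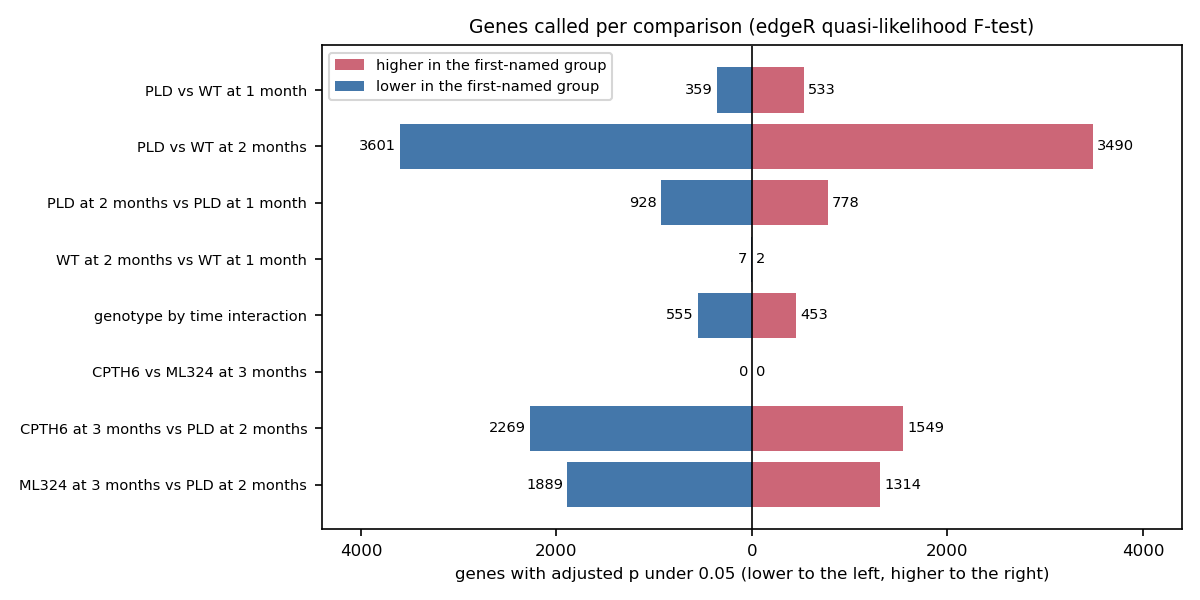
Genes called higher (bars to the right) and lower (bars to the left) at an edgeR adjusted p under 0.05. The 8 comparisons are on the vertical axis and the number of genes on the horizontal axis. The largest total is 7091 for PLD against WT at 2 months (3490 higher and 3601 lower), and CPTH6 against ML324 has 0.

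The genes called at 1 month were set against those called at 2 months. Of the 533 genes higher in PLD at 1 month, 473 (88.7%) were also higher at 2 months, where 105 were the number from independent draws (Fisher's exact test over the genes tested, two-sided, odds ratio 37.1, p = 1.88e-271). For the 359 lower genes, 217 (60.4%) were also lower, against 72.8 from independent draws (odds ratio 6.32, exact p = 2.69e-63). Psca, Msln, Krt19, Krt7 and Pkd2 were among the genes higher at both times, and 1 and 7 genes were called in opposite directions. Genes are not independent replicates, and the shared count of 690 was 2309 without WT replicate 3 at 1 month, 111 without PLD replicate 1, 99 without PLD replicate 2, 261 without WT replicate 1 and 202 without WT replicate 2.

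Change with time within PLD mice was read from 2 months against 1 month. Mmp7, a matrix metalloproteinase of injured epithelium, rose by 4.96 ± 0.70 (edgeR adjusted p = 0.00818), Muc13, a transmembrane mucin, by 4.58 ± 0.98, Tff3 by 4.17 ± 0.89 and Scnn1a, a subunit of the epithelial sodium channel, by 4.22 ± 0.87. Oas3, an interferon-induced antiviral enzyme, rose by 4.24 ± 0.92 and Duoxa2, a maturation factor of the dual oxidases, by 3.85 ± 0.98. The largest falls were in Gkn3 (-4.38 ± 1.00), the imprinted noncoding RNAs Rian (-4.10 ± 0.63) and Meg3 (-3.62 ± 0.56), the gel-forming mucin gene Muc6 (-3.68 ± 0.88), the elastin gene Eln (-3.38 ± 0.62) and Dnase1l3, a secreted nuclease of liver endothelium (-3.31 ± 0.82). Rian and Meg3 lie in one locus of overlapping noncoding transcripts, and the counts carry no strand.

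Endothelial markers fell in PLD between 1 and 2 months as a list, where 0 of 16 rose and 12 fell, against 0 and 15 adjusted over the list alone (camera adjusted p = 1.53e-08, adjusted p = 0.859 with an estimated correlation). Among them were Tek at -2.41 ± 0.48 and Kdr, the receptor of vascular endothelial growth factor, at -2.46 ± 0.51. Sterol synthesis fell too, and 1 of 24 rose and 9 fell, against 1 and 13 adjusted over the list alone (camera adjusted p = 2.24e-05, adjusted p = 0.859 with an estimated correlation). They included Stard4, a cholesterol transporter, at -1.55 ± 0.23, and Insig1 at -1.79 ± 0.31. Mitosis and cell cycle genes were called lower as a list with a median of -0.87 and 0 of 30 members called, 0 adjusted over the list alone (camera adjusted p = 0.000223, adjusted p = 0.859 with an estimated correlation). In the collagens and fibrillar matrix list, 0 of 24 rose and 2 fell, against 0 and 2 adjusted over the list alone (camera adjusted p = 0.00975, adjusted p = 0.859 with an estimated correlation), a call lost without PLD replicate 2 at 2 months (camera adjusted p = 0.0702). For stellate cell and fibroblast markers, 0 of 20 rose and 3 fell, against 1 and 6 adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.859 with an estimated correlation). Among cholangiocyte markers, 2 of 20 rose and 0 fell, against 2 and 0 adjusted over the list alone (camera adjusted p = 0.00446, adjusted p = 0.859 with an estimated correlation). One was the epithelial transcription factor gene Elf3 at 1.31 ± 0.37, and Krt19 at 1.05 ± 0.32 missed the threshold (adjusted p = 0.0626, edgeR). Interferon response genes rose as a list, where 4 of 30 rose and 1 fell, against 13 and 1 adjusted over the list alone (camera adjusted p = 0.000942, adjusted p = 0.859 with an estimated correlation). Among them were Irf7 at 2.69 ± 0.61 and Mx1 at 3.26 ± 0.87, and that call ended without PLD replicate 2 at 2 months (camera adjusted p = 0.185), the library with the highest interferon mean. For fatty acid oxidation, 3 of 24 rose and 0 fell, against 7 and 0 adjusted over the list alone (camera adjusted p = 0.000245, adjusted p = 0.859 with an estimated correlation). For oxidative phosphorylation, 5 of 34 rose and 1 fell, against 6 and 1 adjusted over the list alone (camera adjusted p = 0.00612, adjusted p = 0.859 with an estimated correlation). For ribosomal proteins, 2 of 35 rose and 0 fell, against 8 and 0 adjusted over the list alone (camera adjusted p = 2.01e-06, adjusted p = 0.859 with an estimated correlation). The macrophage and Kupffer cell markers had 3 of 18 members higher and 7 adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.859 with an estimated correlation). That call ended without PLD replicate 1 (0.0982) or replicate 3 (0.0539) at 2 months, or replicate 2 at 1 month (0.118). The ligand gene Wnt10a rose by 2.34 ± 0.33 and Areg by 2.99 ± 0.47.

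Within PLD, 1706 of 17749 genes were called between the times by edgeR, 778 higher and 928 lower at 2 months. Leaving out replicates 1, 2 and 3 at 2 months left 429, 599 and 274 genes, and leaving out replicates 1, 2 and 3 at 1 month left 238, 644 and 135. With the endothelial covariate added after the data were seen, 247 genes were called, 97 of them shared, and 81.5% of the covariate's variance lay between the times.

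In WT mice, the same step from 1 to 2 months called few genes. Serpini1, which encodes the protease inhibitor neuroserpin, fell (change -1.41 ± 0.16, edgeR adjusted p = 0.0434), as did Nrip2 (-1.72 ± 0.23), Itgb6, an epithelial integrin subunit (-1.41 ± 0.19), Col4a5, a basement membrane collagen chain (-1.21 ± 0.17), and Btg1, an antiproliferative gene (-0.86 ± 0.12). Ddah1, an enzyme that degrades an inhibitor of nitric oxide synthesis, rose by 0.95 ± 0.14. Endothelial markers were called higher as a list with a median of 1.21, 0 of 16 called over all genes and 8 adjusted over the list alone (camera adjusted p = 9.1e-09, adjusted p = 0.862 with an estimated correlation). Mitosis and cell cycle genes (median -0.89) were called lower as a list with 0 of 30 called, 0 adjusted over the list alone (camera adjusted p = 3.15e-06, adjusted p = 0.862 with an estimated correlation). Neutrophil markers (median -1.38) were called lower as a list with 0 of 11 called and 4 adjusted over the list alone (camera adjusted p = 0.000705, adjusted p = 0.862 with an estimated correlation). Cholangiocyte markers (median -0.69) were called lower as a list with 0 of 20 called and 1 adjusted over the list alone (camera adjusted p = 2.92e-05, adjusted p = 0.862 with an estimated correlation). Cilium assembly genes (median -0.30) were called lower as a list with 0 of 32 called and 0 adjusted over the list alone (camera adjusted p = 0.00395, adjusted p = 0.862 with an estimated correlation). Without WT replicate 3 at 1 month the call for cholangiocyte markers ended (camera adjusted p = 0.141), and so did that for primary cilium assembly (0.611). Of 17749 genes tested, 9 were called by edgeR (2 higher, 7 lower) and 2674 had an unadjusted p under 0.05, with 642 called by DESeq2 and 159 by limma-voom. The count was 389 without WT replicate 3 and 97 without WT replicate 2 at 1 month, 1 without WT replicate 3 at 2 months, and 0 without WT replicate 1 at 1 month or without WT replicate 1 or 2 at 2 months.

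Whether the genotype difference changed with time was tested as an interaction, a positive value meaning a larger PLD minus WT difference at 2 months. Among the most negative values, Stab2, a scavenger receptor that clears hyaluronan, had an interaction of -5.86 ± 1.20, the lectin genes Clec4g and Clec1b -5.93 ± 1.07 and -5.38 ± 1.13, Oit3 -5.36 ± 1.18, Dnase1l3 -6.24 ± 1.15 and Slc26a10 -5.15 ± 0.54 (adjusted p from 0.00768 to 0.0302, edgeR). At the positive end were Tff3 (5.26 ± 1.3), Areg (4.73 ± 0.71), Mmp7 (4.61 ± 0.88), the brush border myosin gene Myo1a (4.12 ± 0.98) and Dbp, a clock-controlled transcription factor gene (4.00 ± 0.96), with adjusted p from 0.0127 to 0.0403.

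Among endothelial markers, 14 of 16 had a called negative interaction, 16 adjusted over the list alone (camera adjusted p = 5.99e-13, adjusted p = 0.932 with an estimated correlation). They included Kdr at -4.07 ± 0.71 and Tek at -3.79 ± 0.66. Cholangiocyte markers had 4 of 20 called positive and 10 adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.932 with an estimated correlation). Examples were Elf3 at 2.51 ± 0.52 and Krt19 at 1.89 ± 0.46. Ion and water transport genes of bile ducts had 4 of 19 positive, 8 adjusted over the list alone (camera adjusted p = 0.0138, adjusted p = 0.932 with an estimated correlation). In sterol synthesis, 6 of 24 were negative and 11 adjusted over the list alone (camera adjusted p = 3.4e-06, adjusted p = 0.932 with an estimated correlation). Among them were Stard4 at -1.91 ± 0.32 and Insig1 at -2.00 ± 0.42. For fatty acid oxidation, 1 of 24 was positive over all genes and 17 adjusted over the list alone (camera adjusted p = 1.35e-07, adjusted p = 0.932 with an estimated correlation), the called gene being Hadh at 0.77 ± 0.20. Interferon response genes were called positive as a list (median 1.34) with 0 of 30 members called, 0 adjusted over the list alone (camera adjusted p = 0.000236, adjusted p = 0.932 with an estimated correlation). The median of the interferon response list was 0.56 without PLD replicate 2 at 2 months (camera adjusted p = 0.0179). Fibroblast markers were called negative as a list (median -0.79) with 0 of 20 called, 0 adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.932 with an estimated correlation). The call for stellate cell and fibroblast markers ended without WT replicate 3 at 1 month (camera adjusted p = 0.536).

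The interaction was called in 1008 of 17749 genes by edgeR, 453 positive and 555 negative. The count was 244, 575 and 299 without PLD replicates 1, 2 and 3 at 2 months, 217, 603 and 213 without PLD replicates 1, 2 and 3 at 1 month, 100 and 456 without WT replicates 2 and 3 at 2 months, and 516 without WT replicate 1 at 1 month. With the endothelial covariate added after the data were seen, 0 genes were called by edgeR, where 4204 had an unadjusted p under 0.05 without it, and DESeq2 called 2070 and limma-voom 1913 without it. Of that covariate's variance 82.5% lay between the 4 groups, and the median standard error rose from 0.368 to 0.574.

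The next comparison set PLD cells of mice treated with CPTH6 against untreated PLD cells at 2 months. No untreated group of 3 months was analysed here, and the treated libraries form a separate library set, so treatment, age and set changed together. Matrix genes of mesenchymal cells were far lower in the treated group, and granule genes of neutrophils higher. Col1a1 (ENSMUSG00000001506.10, chromosome 11 from 94936224 to 94953042), which encodes a chain of fibrillar collagen, fell (change -4.39 ± 0.53, edgeR adjusted p = 0.000779), from 1122 ± 651 to 55.1 ± 9.19 CPM. Hand2, a transcription factor gene of stellate cells (-4.83 ± 0.39), Dpep1, a dipeptidase (-4.60 ± 0.63), Adamts12, a matrix protease (-4.46 ± 0.58), and the interferon-induced genes Ifit3 (-4.62 ± 1.21) and Ifit3b (-4.43 ± 1.21), close copies of each other between which reads can be shared, were the other largest falls. Ngp (7.84 ± 1.80), Camp (7.08 ± 1.75) and Retnlg (6.97 ± 1.65), made by neutrophils, rose most, with the calprotectin genes S100a9 (5.26 ± 0.97) and S100a8 (5.13 ± 1.03) and the cystine transporter gene Slc7a11 (3.91 ± 0.36).

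Fibrillar matrix and fibroblast genes fell together after CPTH6. Of the collagens and fibrillar matrix genes, 0 of 23 rose and 22 fell, against 0 and 22 adjusted over the list alone (camera adjusted p = 8.34e-14, adjusted p = 0.587 with an estimated correlation). They included Col12a1 at -3.59 ± 0.31 and Tnc, tenascin C, at -4.03 ± 0.33. Of the stellate cell and fibroblast markers, 0 of 20 rose and 17 fell, against 0 and 17 adjusted over the list alone (camera adjusted p = 3.5e-09, adjusted p = 0.616 with an estimated correlation). Examples were Pdgfrb at -3.92 ± 0.42 and Pdgfra at -3.44 ± 0.37, the receptors of platelet-derived growth factor. The basement membrane list was mixed, where 2 of 16 rose and 8 fell, against 2 and 9 adjusted over the list alone (camera adjusted p = 0.00339, adjusted p = 0.616 with an estimated correlation). Hedgehog pathway genes fell beside these markers, and 0 of 14 rose and 10 fell, against 0 and 11 adjusted over the list alone (camera adjusted p = 7.8e-05, adjusted p = 0.25 with an estimated correlation). Among them was the pathway's transcription factor gene Gli1 at -3.60 ± 0.43. Wnt pathway targets also fell as a list, where 2 of 16 rose and 9 fell, against 2 and 9 adjusted over the list alone (camera adjusted p = 0.00298, adjusted p = 0.25 with an estimated correlation). Axin2 went from 41.2 ± 10.6 to 4.03 ± 1.29 CPM (-3.40 ± 0.31). Of cAMP signalling genes, 3 of 24 rose and 14 fell, against 4 and 14 adjusted over the list alone (camera adjusted p = 0.00447, adjusted p = 0.587 with an estimated correlation). Endothelial markers fell as a list, where 0 of 16 rose and 9 fell, against 0 and 13 adjusted over the list alone (camera adjusted p = 0.000248, adjusted p = 0.673 with an estimated correlation). They included the scavenger receptor gene Stab1 at -2.40 ± 0.45. Among macrophage and Kupffer cell markers, 0 of 17 rose and 8 fell, against 0 and 9 adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.673 with an estimated correlation). One was Cd163 at -3.39 ± 0.54, and the call for macrophage and Kupffer cell markers ended without PLD replicate 1 (0.0746) or CPTH6 replicate 1 (0.0629). Neutrophil markers rose as a list, where 9 of 13 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 3.8e-05, adjusted p = 0.634 with an estimated correlation). Their mean was 1.44 log2 CPM in CPTH6 replicate 1 against 4.67 and 5.15 in the other 2.

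Stress defence and mitochondrial transcripts were higher after CPTH6, and interferon genes lower. Of the NRF2 genes, 10 of 21 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 0.000104, adjusted p = 0.634 with an estimated correlation). Among them were Srxn1, sulfiredoxin (ENSMUSG00000032802.8, chromosome 2 from 152105516 to 152111376), at 1.97 ± 0.15 from 30.3 ± 5.03 to 123 ± 16.4 CPM, the thioredoxin reductase gene Txnrd1 at 1.03 ± 0.13 and the haem oxygenase gene Hmox1 at 1.15 ± 0.24. In the unfolded protein response, 8 of 24 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 0.00298, adjusted p = 0.634 with an estimated correlation). They included the chaperone gene Dnajb9 at 1.13 ± 0.11 and the transcription factor gene Atf4 at 0.89 ± 0.16. Of mitochondrially encoded mRNAs, 8 of 12 rose and 0 fell, against 11 and 0 adjusted over the list alone (camera adjusted p = 5.64e-07, adjusted p = 0.25 with an estimated correlation). They included mt-Nd4, a subunit of respiratory complex I, at 0.57 ± 0.11 from 917 ± 84.1 to 1410 ± 90.3 CPM, and mt-Co3, a subunit of cytochrome oxidase, at 1.19 ± 0.16. The level of mt-Co3 was 4.21 ± 0.383 CPM in PLD at 2 months, and reads that also fit nuclear copies of the mitochondrial genome are not counted. Among interferon response genes, 0 of 30 rose and 21 fell, against 0 and 25 adjusted over the list alone (camera adjusted p = 3.8e-05, adjusted p = 0.673 with an estimated correlation). Among them was Ifit2 at -2.68 ± 0.41. The median of the interferon response list was -1.87, and -1.03 without PLD replicate 2, the library with the highest interferon mean (camera adjusted p = 8.24e-05). In cholangiocyte markers, 10 of 20 rose and 1 fell, against 11 and 1 adjusted over the list alone (camera adjusted p = 0.000248, adjusted p = 0.587 with an estimated correlation). They included Epcam at 0.85 ± 0.14 and Spp1, osteopontin, at 1.16 ± 0.20, while Krt19 at 0.24 ± 0.16 was not called (adjusted p = 0.306, edgeR). NF-kB pathway targets had 8 of 24 members higher and 2 lower, 12 and 2 adjusted over the list alone (camera adjusted p = 0.00266, adjusted p = 0.673 with an estimated correlation). The cell cycle inhibitor gene Cdkn1a rose by 1.36 ± 0.16 and the AP-1 subunit gene Fosl1 by 2.23 ± 0.13. Pkd1 fell (change -0.92 ± 0.10) and Pkhd1 rose by 0.79 ± 0.17. The genes of the enzymes that CPTH6 inhibits were not called, with Kat2a at -0.47 ± 0.17 (adjusted p = 0.0699, edgeR) and Kat2b at 0.38 ± 0.14 (0.0842). Histone demethylases had 7 of 18 higher and 8 adjusted over the list alone (camera adjusted p = 0.0164, adjusted p = 0.673 with an estimated correlation), and the call for histone demethylases ended without PLD replicate 3 (0.0659).

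CPTH6 against PLD at 2 months gave 3818 called genes of 16502 by edgeR, 1549 higher and 2269 lower. The count was 2530 without PLD replicate 3, 2496 without CPTH6 replicate 1 and 2490 without CPTH6 replicate 3. With the mean of the fibroblast markers as a covariate, added after the data were seen, edgeR called 0 genes, against 6008 with an unadjusted p under 0.05 without it. As 99.3% of that covariate's variance lay between the groups, it nearly repeats the treatment, and the loss of calls was fixed by the design.

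ML324-treated PLD cells were compared with the same untreated PLD cells, with the same joint change of age and library set. Mt2, a metallothionein, fell (change -4.96 ± 0.37, edgeR adjusted p = 0.000267), with the matrix gene Thbs2, thrombospondin-2 (-4.23 ± 0.51), Col1a1 (-4.03 ± 0.52, to 68.3 ± 34.3 CPM), Cd163 (-3.99 ± 0.57), Hand2 (-3.98 ± 0.38) and Art4 (-3.89 ± 0.33). The rises were led by Retnlg (6.19 ± 1.64), Ngp (5.67 ± 1.75), S100a9 (4.88 ± 0.95) and S100a8 (4.77 ± 1.02), followed by Acod1, the enzyme that makes itaconate in activated myeloid cells (3.73 ± 0.43), and Ivl, involucrin, a protein of the squamous cell envelope (3.71 ± 0.36).

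The matrix lists fell after ML324 as well. Of the collagens and fibrillar matrix genes, 0 of 23 rose and 21 fell, against 0 and 22 adjusted over the list alone (camera adjusted p = 1.6e-13, adjusted p = 0.616 with an estimated correlation), Col12a1 at -3.16 ± 0.31 being one of them. Of the stellate cell and fibroblast markers, 0 of 20 rose and 16 fell, against 0 and 18 adjusted over the list alone (camera adjusted p = 6.36e-10, adjusted p = 0.616 with an estimated correlation). One was Pdgfrb at -3.42 ± 0.41. In the basement membrane list, 1 of 16 rose and 8 fell, against 2 and 10 adjusted over the list alone (camera adjusted p = 0.00086, adjusted p = 0.616 with an estimated correlation). Among matrix proteases and inhibitors, 3 of 22 rose and 12 fell, against 4 and 13 adjusted over the list alone (camera adjusted p = 0.00712, adjusted p = 0.681 with an estimated correlation). For TGF-beta pathway and targets, 2 of 20 rose and 9 fell, against 3 and 11 adjusted over the list alone (camera adjusted p = 0.0163, adjusted p = 0.474 with an estimated correlation). Hedgehog genes (0 of 14 rose and 6 fell, against 0 and 9 adjusted over the list alone) were called lower (camera adjusted p = 0.000197, adjusted p = 0.456 with an estimated correlation), and Gli1 stood at -2.84 ± 0.41. Of the Wnt pathway targets, 1 of 16 rose and 9 fell, against 1 and 9 adjusted over the list alone (camera adjusted p = 0.00763, adjusted p = 0.456 with an estimated correlation). Axin2 stood at -3.08 ± 0.31. Of cAMP signalling genes, 0 of 24 rose and 11 fell, against 1 and 14 adjusted over the list alone (camera adjusted p = 0.000581, adjusted p = 0.474 with an estimated correlation). Endothelial markers (0 of 16 rose and 4 fell, against 0 and 7 adjusted over the list alone) were called lower (camera adjusted p = 0.00015, adjusted p = 0.731 with an estimated correlation). Without ML324 replicate 2, the library set apart by its markers, the median of the endothelial markers was -2.59, that of the stellate cell and fibroblast markers -3.55 and that of the collagens and fibrillar matrix -3.58, against -1.47, -2.67 and -2.79 with it. The macrophage and Kupffer cell markers (0 of 17 rose and 11 fell, against 0 and 12 adjusted over the list alone) were lower too (camera adjusted p = 0.000128, adjusted p = 0.616 with an estimated correlation). Among them was Gpnmb, a glycoprotein of lipid-laden macrophages, at -1.58 ± 0.24. Neutrophil markers (5 of 13 rose and 0 fell, against 9 and 0 adjusted over the list alone) were called higher (camera adjusted p = 0.000327, adjusted p = 0.731 with an estimated correlation). Their mean was 1.35 log2 CPM in ML324 replicate 3 against 2.73 and 4.47 in the other 2. Among NRF2 genes, 9 of 21 rose and 0 fell, against 10 and 0 adjusted over the list alone (camera adjusted p = 5.61e-05, adjusted p = 0.616 with an estimated correlation). Examples were Srxn1 at 2.30 ± 0.15 to 149 ± 15.9 CPM and Slc7a11 at 3.52 ± 0.36. Interferon response genes fell as a list, where 0 of 30 rose and 12 fell, against 0 and 18 adjusted over the list alone (camera adjusted p = 0.000351, adjusted p = 0.796 with an estimated correlation). The median of the interferon response list was -1.35, and -0.49 without PLD replicate 2 (camera adjusted p = 0.00972). In cholangiocyte markers, 4 of 20 rose and 0 fell, against 6 and 0 adjusted over the list alone (camera adjusted p = 0.00391, adjusted p = 0.616 with an estimated correlation), and Epcam rose by 0.75 ± 0.14. Fosl1 rose by 2.13 ± 0.13. Pkd1 fell (change -0.68 ± 0.10) and Pkhd1 rose by 0.74 ± 0.17. The demethylase genes Kdm4a (-0.04 ± 0.13, adjusted p = 0.836, edgeR) and Kdm4c (0.03 ± 0.10), whose proteins ML324 inhibits, were not called, while the demethylase gene Kdm7a rose by 0.55 ± 0.14 and the acetyltransferase gene Kat5 by 0.48 ± 0.08.

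ML324 against PLD at 2 months gave 3203 called genes of 16502 by edgeR, 1314 higher and 1889 lower. The count was 2007 without PLD replicate 3, 1939 without ML324 replicate 3, 372 with the macrophage marker covariate, and 0 by edgeR with the fibroblast marker covariate added after the data were seen, against 5585 with an unadjusted p under 0.05 without it. Of the variance of these covariates 74.5% and 84.4% lay between the groups, so a loss of calls was expected.

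**Figure D3:**
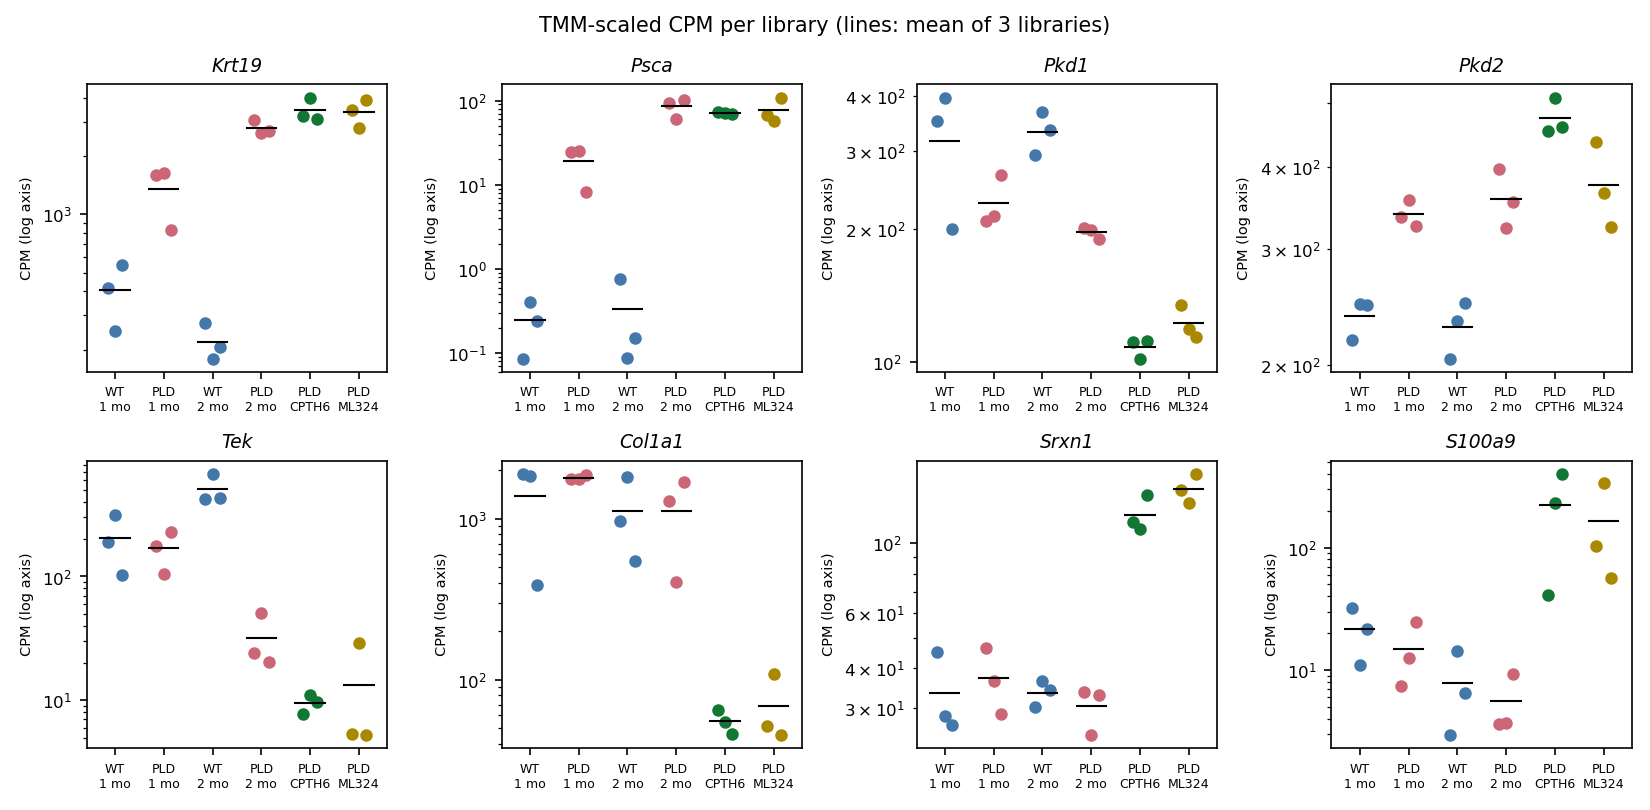
TMM-scaled CPM (vertical log axes) of Krt19, Psca, Pkd1, Pkd2, Tek, Col1a1, Srxn1 and S100a9 in each of the 18 libraries, by group (horizontal axes), with lines at the mean of 3. Col1a1 averages 1122 CPM in PLD at 2 months and 55.1 and 68.3 in the CPTH6 and ML324 groups.

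The treated groups were compared with each other at the same month, which tests how cells treated with CPTH6 differed from those treated with ML324. No single gene was called by edgeR with the filter on low counts, against 268 by DESeq2 and 232 by edgeR without that filter, and Col1a1 stood at -0.36 ± 0.30 and Krt19 at -0.03 ± 0.16 (CPTH6 minus ML324). Gene lists differed by camera. In mitosis and cell cycle progression, 0 of 29 members were called over all genes and 13 higher in CPTH6 adjusted over the list alone (camera adjusted p = 4.74e-10, adjusted p = 0.735 with an estimated correlation). Among them was Cdk1 at 1.06 ± 0.26. Immediate early genes had 0 of 23 and 9 adjusted over the list alone (camera adjusted p = 2.07e-08, adjusted p = 0.662 with an estimated correlation). For fatty acid oxidation, 0 of 24 were called and 9 adjusted over the list alone (camera adjusted p = 1.52e-06, adjusted p = 0.662 with an estimated correlation). They included Ppargc1a, a coactivator of mitochondrial biogenesis, at 0.75 ± 0.11. Mitochondrially encoded mRNA had 0 of 13 and 6 adjusted over the list alone (camera adjusted p = 1.35e-07, adjusted p = 0.62 with an estimated correlation). One was mt-Nd4 at 0.57 ± 0.10. NF-kB pathway targets (0 of 24, 2 adjusted over the list alone) were called higher (camera adjusted p = 0.000424, adjusted p = 0.748 with an estimated correlation), and the adhesion molecule gene Icam1 stood at 0.91 ± 0.18. Macrophage and Kupffer cell markers (0 of 17, 4 adjusted over the list alone) were called higher as well (camera adjusted p = 0.000148, adjusted p = 0.748 with an estimated correlation). Interferon response genes (0 of 30, 2 adjusted over the list alone) were called lower in CPTH6 (camera adjusted p = 0.00039, adjusted p = 0.9 with an estimated correlation). Among them was Isg15 at -0.91 ± 0.22. Sterol synthesis (0 of 24, 0 adjusted over the list alone) was also called lower (camera adjusted p = 0.00123, adjusted p = 0.9 with an estimated correlation), but not without ML324 replicate 3 (camera adjusted p = 0.519). Gpnmb (1.29 ± 0.21), the complement gene C4b (-1.05 ± 0.14), Kat2a (-0.01 ± 0.13) and Kdm4a (-0.24 ± 0.13) were not called by edgeR. Of the 11 genes named for this comparison, 7 were called by DESeq2 and 6 by edgeR without the filter on low counts, Gpnmb and C4b in both.

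Over 15989 genes, edgeR called 0 between the treatments, 2008 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 268. A count of 0 does not show that the compounds act alike. The standard errors above leave room for differences, and planted 2-fold changes were called in 46.3% of genes here.

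The 533 genes higher and 359 lower in PLD at 1 month were then followed into the treated groups, read against untreated PLD at 2 months. After CPTH6 the higher genes had a median change of 0.175 over the 529 measured, with 135 called higher and 33 lower (camera adjusted p = 1.09e-06, and adjusted p = 0.178 with an estimated correlation). The lower genes had a median of -0.436 over 317, with 7 higher and 96 lower (camera adjusted p = 5.01e-07, and adjusted p = 0.178 with an estimated correlation). After ML324 the higher genes had a median of 0.217, with 111 higher and 25 lower (camera adjusted p = 7.21e-08, and adjusted p = 0.143 with an estimated correlation). The lower genes had a median of -0.529 there, with 5 higher and 95 lower (camera adjusted p = 1.43e-10, and adjusted p = 0.143 with an estimated correlation). Both comparisons share the same 3 untreated libraries, so their agreement is partly built in, and age and library set changed with the compound. By the directional fry test the genes higher in PLD at 1 month were called after CPTH6 (fry adjusted p = 0.0235) and ML324 (0.0132), and the lower genes likewise (0.0105 and 0.00426). The call for the higher genes ended after CPTH6 without PLD replicate 2 (fry adjusted p = 0.0755), PLD replicate 3 (0.0596) or CPTH6 replicate 1 (0.0783), and after ML324 without PLD replicate 2 (0.0545). The lists came from a fit of all 12 untreated libraries, those of PLD at 2 months included, so they are not independent of the baseline. The macrophage and Kupffer cell markers fell in both treated groups as well (medians -0.72 and -1.58).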

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

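The tests on library composition and scaling, and the alternatives with endothelial or fibroblast markers as covariates, were chosen after the results were seen. So was Dbp as the target of the time of day test. The other splits of the libraries were chosen before. The interaction of genotype and time was called in 1008 genes by edgeR, which flagged it, and in 100 genes without WT replicate 2 at 2 months. Of 100 splits drawn, the real one included, 6 gave as many genes, and the highest of the others gave 5666. All 5 of the others kept the libraries of the 2-month groups together, which carries the genotype difference of 2 months into their interaction, and the 91 splits that mixed these groups gave at most 1 gene. The splits therefore cannot tell whether chance gives such a count.

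Genes at both ends of the interaction are given with their values. Tff3 had an interaction of 5.26, from a PLD minus WT difference of 1.10 at 1 month to 6.36 at 2 months. Areg (4.73) went from 1.18 to 5.91, Mmp7 (4.61) from -1.18 to 3.42, Myo1a (4.12) from -0.96 to 3.15 and Dbp (4.00) from -0.36 to 3.63. Dnase1l3 (-6.24) went from 1.75 to -4.49, Clec4g (-5.93) from 1.39 to -4.54, Stab2 (-5.86) from 1.66 to -4.20, Clec1b (-5.38) from 1.16 to -4.22, Oit3 (-5.36) from 1.52 to -3.84 and Slc26a10 (-5.15) from 0.34 to -4.81.

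The first pattern weighed is the rise of cholangiocyte markers with the fall of endothelial markers in PLD at 2 months. A larger share of epithelial cells as the whole cause would raise the 20 cholangiocyte markers alike only if no other captured cell expressed them. Their changes differed, as Sorbs2 changed by -0.13 and Krt7 by 4.02, with an SD that was 4.09 times the median standard error. The limit of 2 times for unlike changes was set after the data were seen. A marker also expressed in other cells would rise less. This spread therefore cannot exclude a larger epithelial share as the whole cause. Of the 20 markers 6 stand on another list as well, and the other 14 had an SD of 4.48 times theirs. Scaling as the whole cause is excluded by the same 4.09, since one factor per library moves every gene alike. The endothelial changes, from -4.54 for Clec4g to -2.51 for Eng, had an SD of 1.21 times their standard error, so a smaller share of endothelial cells may account for them, and 2 of the 16 markers stand on another list as well. The most abundant of them, Vwf and Eng, had 2693 ± 995 and 1549 ± 517 CPM (SD, n = 3) in WT and 276 ± 151 and 276 ± 50.5 in PLD at 2 months, although capture on EpCAM beads would remove endothelial cells. Genes that differ between genotypes inside cholangiocytes, such as Krt7, stay open as a biological explanation beside a change in the other cells.

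A second pattern is the lower level of fibroblast and collagen genes in the treated groups. With fewer fibroblasts as the whole cause the 20 markers would fall alike only if the remaining cells did not express them. The SD of their changes was 2.57 times the median standard error after CPTH6 and 2.14 times after ML324. Fbln2 changed by -0.07 and Col1a1 by -4.39 after CPTH6. The same limit for unlike changes, set after the data were seen, lies just under the ML324 values. A marker that the remaining cells express would fall less, so this spread cannot exclude a loss of fibroblasts as the whole cause. A smaller share of fibroblasts, which the EpCAM beads would also remove, may be part or all of it. The most abundant members, Col3a1 and Col1a2, went from 1822 ± 1120 and 1200 ± 572 CPM to 119 ± 21.7 and 63.6 ± 15.4 after CPTH6. Of the 20 markers 8 stand on other lists, and the other 12 had an SD of 2.56 times their standard error after CPTH6 and 2.02 times after ML324. Age or the separate library set in place of the treatment cannot be told apart from it, because 0 untreated libraries of 3 months were among those compared. An effect of the compounds on these genes stays open and untested.

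The third pattern is Dbp, a gene under control of the circadian clock. Collection at another time of day may account for it: the other genes of its phase (Nr1d1, Nr1d2, Per3, Tef, Hlf and Ciart) had a median interaction that was 3.26 higher than that of the opposite phase (Arntl, Npas2, Clock and Nfil3), as that explanation needs. Per3 stood at 3.77 and Hlf at 2.97, Arntl at -1.82 and Npas2 at -1.58, with Nr1d1 at 0.06 and Nfil3 at 0.39. WT replicate 3 at 1 month differed from its group, with Per3 at 83.1 CPM against 11.4 and 10.3, and Arntl at 6.44 against 34.8 and 52.5. Without that library Per3 stood at 2.07, Hlf at 2.47, Arntl at -1.34, Npas2 at -1.06 and Dbp at 3.13, and the difference between the phases was 2.45, the lowest with any library left out. Dbp kept its call there (adjusted p = 0.041) but lost it in 8 of the 12 fits without one library, up to an adjusted p = 0.106 without WT replicate 2 at 2 months. Dbp itself was 5.13 ± 4.64 CPM in WT at 2 months against 52.4 ± 41.3 in WT at 1 month, 40.6 ± 8.79 in PLD at 1 month and 64.0 ± 31.6 in PLD at 2 months. A change of the clock in the cells with genotype was not tested and stays open.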

How the results depend on the processing

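Every alternative with endothelial or fibroblast markers as covariates, and the fit without WT replicate 3 at 1 month and WT replicate 1 at 2 months, was chosen after the data were seen, and the other alternatives before. Counts of called genes within 1.5 times the reported one are not listed, and the cause of a change was not tested unless given.

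At an absolute log2 fold change of at least 1, a stricter threshold by construction, 545 genes were called in PLD against WT at 1 month, 4005 at 2 months, 872 for time in PLD, 1761 for CPTH6 and 1477 for ML324 against PLD at 2 months, and the overlap of the genotype calls was 398. No filter on low counts gave 2194 genes at 1 month, 2818 for time in PLD, 1224 for time in WT, 2282 for the interaction, 232 for CPTH6 against ML324, and an overlap of 1488. The stricter filter gave 29 for time in WT. DESeq2 called 2157 genes at 1 month, 3086 for time in PLD, 642 for time in WT, 2070 for the interaction and 268 between the compounds, with an overlap of 1463. limma-voom with quality weights called 5842, 5525, 159 and 1913 in the first 4 of these. All 18 libraries in one fit gave 1733 at 1 month, 135 for time in WT and 1561 for the interaction, and the 6 libraries compared alone gave 29, 0 for time in WT (fewer libraries) and 3811 for time in PLD.

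With hepatocyte markers as a covariate 360 genes were called at 1 month, 0 for time in WT and 288 for the interaction. Macrophage markers as a covariate gave 2 at 1 month, 4529 at 2 months, 927 for time in PLD, 4 for time in WT, 486 for the interaction, 1801 for CPTH6 and 372 for ML324. With endothelial markers the counts were 2033 at 1 month, 183 at 2 months, 247 for time in PLD, and 0 for time in WT and for the interaction, and with fibroblast markers added 3326, 334, 601, 0 and 0. Fibroblast markers alone left 0 genes for CPTH6 and 0 for ML324. Endothelial markers at 2 months and fibroblast markers after treatment nearly repeat the groups (93%, 99.3% and 84.4% of their variance), so these losses say little. Zero counts here are by edgeR, beside 2674 (time in WT), 4204 (interaction), 6008 (CPTH6) and 5585 (ML324) genes with an unadjusted p under 0.05 in the reported fits. Under the endothelial covariate 3 genes named at 2 months changed sign: Alb to -1.53 (adjusted p = 0.39), Pkd1 to 0.40 (adjusted p = 0.565) and Sec63 to 0.32 (adjusted p = 0.583). Under the fibroblast covariate Cd163 (0.32, adjusted p = 0.937) and Stab1 (0.12, adjusted p = 0.967) changed sign for CPTH6. Without WT replicate 3 at 1 month and WT replicate 1 at 2 months, 3541 genes were called at 1 month, 3861 for time in PLD and 184 for time in WT, with an overlap of 2555.

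The replicate numbers were tried as a block, with correlations of the residuals of same-numbered libraries from -0.23 to 0.26. The own number matched best in 3 of 3 libraries for time in WT (0.08 to 0.20) and for ML324 against PLD (0.03 to 0.11), and in 0 of 3 for genotype at either time and for time in PLD. The block gave 965 genes for time in PLD, 426 for the interaction, 1 between the compounds and 0 for time in WT.

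Leaving out each library in turn gave 99 to 3485 genes in PLD against WT at 1 month (highest without WT replicate 3, lowest without PLD replicate 2), 5324 to 6350 at 2 months, 135 (without PLD replicate 3 at 1 month) to 644 for time in PLD, and 0 to 389 for time in WT. The interaction gave 100 (without WT replicate 2 at 2 months) to 1413, CPTH6 against ML324 0 to 3 (3 without ML324 replicate 3), CPTH6 2490 (without CPTH6 replicate 3) to 3284, and ML324 1939 (without ML324 replicate 3) to 3043. The overlap was 99 to 2309. Lists called ranged over 14 to 20 at 1 month, 14 to 17 at 2 months, 10 to 16 for time in PLD, 14 to 24 for time in WT, 12 to 19 for the interaction, 10 to 18 between the compounds, 19 to 23 for CPTH6 and 15 to 23 for ML324. The genes higher in PLD at 1 month had medians of 0.150 to 0.199 after CPTH6 and 0.154 to 0.248 after ML324, and the lower genes -0.527 to -0.408 and -0.658 to -0.426.

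With an estimated correlation 0 lists were called in each of the 8 comparisons. Directional fry called 1 list at 1 month, 0 for time in PLD, 0 for time in WT, 2 for the interaction, 2 between the compounds and 13 for CPTH6. No filter gave 23 lists at 1 month, 26 at 2 months, 26 for time in PLD, 35 for time in WT and 27 for the interaction. Of the 22 genes named for time in PLD, 9, 9 and 13 lost their call without PLD replicates 1, 2 and 3 at 2 months, and 13, 10 and 14 without those at 1 month. Of the 18 named for the interaction, 11, 4 and 11 lost it without PLD replicates 1, 2 and 3 at 2 months, 11, 6 and 11 without those at 1 month, 4, 15 and 8 without WT replicates 1, 2 and 3 at 2 months and 9 without WT replicate 1 at 1 month. All 6 named for time in WT lost it without WT replicate 1 at 1 month or without any of the 3 WT libraries at 2 months. At most 3 of 38 at 2 months (without WT replicate 2), 3 of 37 for CPTH6 (without PLD replicate 2 or 3) and 3 of 27 for ML324 (without PLD replicate 1 or 3) lost it. In simulated counts a 2-fold change was called in 4.48% of planted genes in the interaction and 19.4% for time in WT.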

Other observations

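The splits named here were chosen before the data were examined, and no test in this part was chosen after. Mesothelial markers divided in PLD at 2 months, where 2 of 9 rose and 7 fell by edgeR, with a median of -3.02 and no call as a list (camera adjusted p = 0.115), and Msln was one of those that rose. Notch pathway genes had 8 of 17 lower and 1 higher in PLD at 2 months (camera adjusted p = 0.0879). Genes of primary cilium assembly, the organelle in which polycystins act, were 7 higher and 6 lower of 32 at 2 months, with no call as a list (camera adjusted p = 0.585), and 0 of 32 were called at 1 month by edgeR. Of the histone acetyltransferases, 6 of 18 were higher in PLD at 2 months and 0 lower, and 4 were higher after CPTH6 and 4 after ML324, with no call as a list in any of these comparisons. The Y-linked gene Ddx3y was present in all 18 libraries, between 84.7 and 191 CPM, and its group means ran from 97.5 ± 11.1 in PLD at 2 months to 167 ± 13.6 in PLD at 1 month.

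For the comparisons of 3 against 3 libraries, the 6 libraries were refitted under each of the 10 ways of dividing them, which are too few for a share under 0.05. The real division gave 29 genes and the highest other 2 for PLD against WT at 1 month (1 of 10 as large), 7359 and 0 at 2 months, 3811 and 0 for time in PLD, 3930 and 0 for CPTH6 and 2340 and 0 for ML324 against PLD at 2 months. For time in WT the real division gave 0 and every other 0 by edgeR in this fit, where 9 genes were called and 2674 had an unadjusted p under 0.05 among the 12 libraries, and DESeq2 called 642 and limma-voom 159. Between CPTH6 and ML324 the real division gave 0 and the highest other 48, against 2008 with an unadjusted p under 0.05, 268 by DESeq2 and 0 by limma-voom.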
